A study of Drosophila melanogaster with 6 samples.

How the data were processed

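The series compared heart/nephrocyte complexes of adult female flies fed 0.1 M glucosamine with those of flies fed 1.0 M sucrose for 21 days, on 3 Affymetrix arrays per group. Per the labels' protocols, total RNA was purified with Trizol and an RNeasy MinElute kit, and biotinylated cRNA was prepared by the standard Affymetrix protocol. The authors deposited 1 intensity per probe set and array, on a linear scale. The method of summarising probes, of background correction and of normalization was not given in the sources used here. The deposited intensity values ran from 4.32 to 46624, and their upper quartile lay between 222 and 237 in all arrays, so they were treated as already normalized and used as deposited. Low intensities carry little information, and differences of genes near the background are understated by the pseudocount. Groups and replicate numbers came from the sample titles.

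Of 18952 probe sets, 183 were controls. By the platform annotation 13645 probe sets had 1 gene symbol, 402 had several and 4722 had none, controls not included. Of those with 1 symbol, 13543 matched a RefSeq gene by Entrez identifier, and 0 symbols changed. The RefSeq table, of the assembly Release 6 plus ISO1 MT, served only for names and for which genes neighbour each other. Control probe sets and those with several symbols were left out of the tests. Each of the 11981 genes was represented by its probe set with the highest mean, and 1094 genes had more than 1. This left 16703 genes and unnamed probe sets, of which the 40% with the lowest mean were left out and 10022 were tested, 8766 of them with a symbol. Among 148 other probe sets of genes past the threshold, 131 had the same sign, 17 the opposite sign, and 1 of these passed the threshold.

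Differences are glucosamine minus sucrose on the scale log2(intensity + 16), which understates the change of genes with low intensity. They were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Errors of intensities are SD over 3 arrays, and errors of log2 differences are the SE of the fit. Gene lists with at least 5 tested members were tested with camera, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over 29 lists, and beside it with camera with an estimated correlation and with fry. Camera called 8 lists, 7 down and 1 up, and 0 with an estimated correlation, where 1 had an unadjusted p under 0.05. Fry, which asks whether a list's genes move on balance one way and does not compare them with other genes, called 9 lists, and 23 in either direction. Counts within lists are given over all tested genes and adjusted over the list alone. The lists covered nephrocyte, heart, hexosamine, sugar, lipid, mitochondrial, signalling, clock, translation, protein turnover, stress, matrix and immune genes, and markers of gut, fat body, ovary, neurons and glia, hemocytes and epidermis. They held 836 members, of which 646 were on the array.

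The genes named in the text were chosen by a rule. It took the 12 largest rises and the 12 largest falls among genes past the threshold whose groups did not overlap, applied to genes with a symbol. It added sns, kn, kirre, Gfat1, Gfat2, sxc and Oga whatever their result, and up to 4 members with the smallest unadjusted p in each list. The groups, lists, rule and tests were fixed before the data were examined, and alternatives and tests added later are named where they are given.

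The gene test was tested on simulated data made from the means and spreads of the 10022 genes, with 50 genes changed at each size. It recovered 2% of genes changed by 0.5 on the log2 scale and 58% of those changed by 1. It recovered 90% of those changed by 2 and 100% of those changed by 4, with 5 false calls. With nothing changed it made 0 calls. The adjustment depends on how many genes change, and 1858 were called in the data, so these shares may not apply there. The list test called the shifted list and 0 others. The simulated genes varied independently, so this could not show calls that come from correlation within a list. In the data that correlation was estimated at 0.252 for oxidative phosphorylation.

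The alternatives were quantile normalization, centring on the median, cyclic loess, no filter, a filter on 60%, the mean of a gene's probe sets, a variance trend with a robust prior, the replicate number as a block, array weights, log2(intensity + 1), each array left out in turn, all probe sets separately, and an unadjusted p under 0.05. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.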

Results

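Gene expression was measured in heart/nephrocyte complexes dissected from adult female Drosophila melanogaster. In the fly, nephrocytes are filtering and endocytic cells, and the pericardial nephrocytes lie along the heart tube. The series held 6 single-channel Affymetrix arrays in 2 groups of 3. In 1 group the flies had eaten food with 0.1 M glucosamine for 21 days, and in the other food with 1.0 M sucrose for the same time. Glucosamine is an amino sugar that enters the hexosamine pathway, which makes the sugar donor for protein glycosylation and for O-GlcNAc. The labels name 30 adult females but do not say whether each array held 30 or whether the arrays came from separate sets of flies, so p-values measure only the spread between these samples, which may be technical. No arm on standard food was analysed here, so each difference is between these diets, which also differ in sugar concentration. The upper quartile of intensity lay between 222 and 237 in all 6 arrays, and 6321 to 6435 of 18952 probe sets had an intensity over 100. The number of arrays limits the precision of every value.

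The comparison asked how expression in the complexes differed between flies that had been fed glucosamine and flies that had been fed sucrose. Of 19 tested genes of nephrocyte filtration and uptake, 7 were lower after glucosamine past the threshold, none were higher and 12 did not pass (camera adjusted p = 8.3e-04 with a preset correlation, adjusted p = 0.60 with an estimated correlation). The intensity of sns, which encodes the fly nephrin of the slit diaphragm, was 96.6 ± 3.13 (SD, n = 3) in glucosamine-fed and 486 ± 185 (SD, n = 3) in sucrose-fed flies. Amnionless, whose product partners cubilin in protein uptake, had an intensity of 2727 ± 814 against 13303 ± 2031 (SD, n = 3 each). Of 32 tested genes of oxidative phosphorylation, 19 were lower and none were higher (camera adjusted p = 3.1e-09 with a preset correlation, adjusted p = 0.60 with an estimated correlation). The count of 19 was between 4 and 16 without 1 array and 0 without glucosamine replicate 3 and sucrose replicate 1, with medians of −0.71 to −0.59. Genes that rose included the triglyceride synthesis enzyme gene Dgat2, from 25.9 ± 14.0 to 861 ± 423 (SD, n = 3 each).

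Across 10022 genes and unnamed probe sets tested with limma, 1858 passed an adjusted p of 0.05, of which 995 were higher and 863 lower in glucosamine-fed flies. A difference of over 2-fold was found for 591 of the higher and 369 of the lower ones. A rise of over 8-fold was found for 35 and a fall of that size for 2. All 1858 had 3 arrays of one group entirely above the 3 of the other, as did 39.0% of everything tested, where chance gives 10%. Pearson correlations across genes, which are not independent replicates, were 0.972 to 0.978 within the glucosamine group, 0.973 to 0.978 within the sucrose group and 0.931 to 0.952 between groups. An exact permutation test of 3 arrays against 3 cannot give a two-sided p below 0.1, so the calls rest on the spread that limma pools across genes. The count was 782 without glucosamine replicate 1, 1084 without glucosamine replicate 3, 1161 without sucrose replicate 1, 1087 without sucrose replicate 2 and 1229 without sucrose replicate 3.

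The largest rise among genes with a symbol was that of CG31288, with a log2 difference of 6.01 ± 0.53 (SE; adjusted p = 0.00208). Its intensity was 2517, 1225 and 5973 in the 3 glucosamine arrays and 25.4 ± 4.24 (SD, n = 3) in the sucrose arrays. With glucosamine replicate 3 and sucrose replicate 1 both left out it was 5.34, below CG8620 (6.16) and CG33468 (5.65), so its rank depended on the arrays used. CG31288, CG6908, CG32195 and CG13659 belong to the ecdysteroid kinase-like family, and their log2 differences were 6.01, 4.91, 4.78 and 4.63. CG32195 had the smallest adjusted p of them, 0.00025, with an intensity of 4821 ± 940 against 158 ± 17.6 (SD, n = 3 each). The other genes among the 12 largest rises were CG8620 (5.74), CG33468 (5.74), CG4269 (4.95), CG6071 (4.91), Dgat2 (4.31), CG7763 (4.16), Gagr (4.12) and CG12766 (4.04). The largest fall was that of lectin-33A, a C-type lectin gene, whose intensity was 399.7 ± 63.1 against 11102 ± 1452 (SD, n = 3 each; log2 difference −4.74 ± 0.17, SE; adjusted p = 0.00025). The next falls were those of CG6484 (−3.01), CG3984 (−2.93) and tobi (−2.75), an alpha-glucosidase-like gene known as a target of insulin-producing cells. They were followed by CG33296 (−2.74), CG13086 (−2.73), CG13077 (−2.70), CG16756 (−2.68), CG13793 (−2.68), CG14823 (−2.65), the metallothionein gene MtnB (−2.64) and Agpat4 (−2.61). Over the alternatives CG14823 ran from −3.04 to −1.70, and a second probe set of it had −2.15, so its rank depended on the setting. Of these falls, 3 did not pass in every alternative: CG13077 passed in 12 of 17, MtnB in 15 and Agpat4 in 16, with adjusted p of up to 0.123, 0.0926 and 0.0528. Among probe sets without a symbol, the largest rise was 6.08 and the largest fall −2.77 on the log2 scale. Of the 99 named genes past the threshold, 59 passed with each of the 6 arrays left out in turn.

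**Figure D1:**
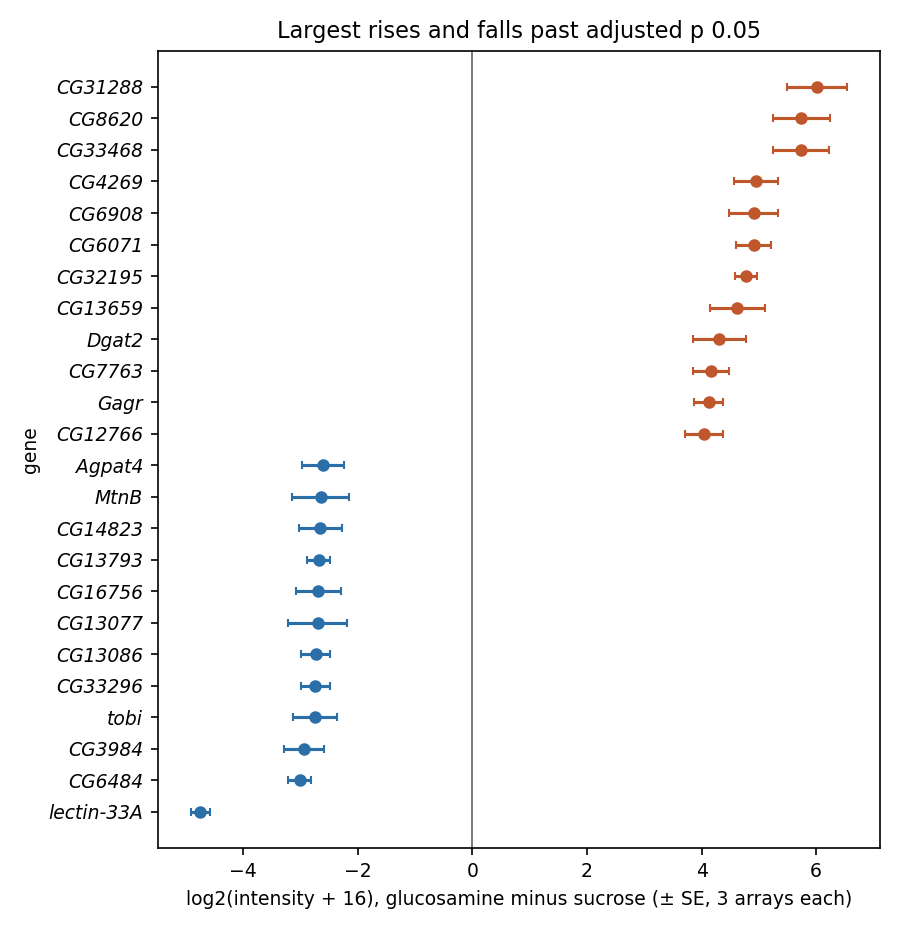
The horizontal axis is the difference of log2(intensity + 16) between glucosamine-fed and sucrose-fed flies for the 12 largest rises and 12 largest falls, and bars are SE with 3 arrays per group. The rises lie between 4.04 and 6.01 and the falls between −4.74 and −2.61.

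In the list of slit diaphragm and nephrocyte uptake genes, 7 of 19 tested members fell, none rose and 12 did not pass. Adjusted over the list alone, 9 fell and none rose. Cubn2 and Cubn, which encode cubilin-type uptake receptors, fell by 2.16 ± 0.17 and 1.66 ± 0.19 on the log2 scale (SE), and a second probe set of Cubn2 fell by 2.41. Amnionless fell by 2.31 ± 0.24 and sns by 2.10 ± 0.25 (SE; limma adjusted p = 0.00345 and 0.00463). The transcription factor gene kn, also called collier, fell from 459 ± 228 to 88.2 ± 15.8 (SD, n = 3 each; adjusted p = 0.00962). The log2 difference of kn was −2.10, and it ran from −2.39 to −1.05 over 17 alternatives, past the threshold in each. The other members that fell, named after their values were seen, were Klf15 (−1.79), a transcription factor gene of nephrocyte differentiation, and zyd (−0.57, adjusted p = 0.0495). The other slit diaphragm gene named in advance, kirre, had a log2 difference of −0.63 ± 0.62 (SE; adjusted p = 0.527), within the spread of its arrays. The list's median difference was −0.63, and camera with a preset correlation gave an adjusted p of 8.3e-04 (adjusted p = 0.60 with an estimated correlation). With glucosamine replicate 3 and sucrose replicate 1 both left out, a setting chosen after seeing the data, 4 members fell, and Cubn and sns had log2 differences of −1.70 and −2.21 (adjusted p = 0.0501 and 0.0533), while the list's median was −0.39 against −0.63. The 5′ minus 3′ signals of the eIF-4a, GAPDH and 18S rRNA controls were lower in the glucosamine arrays as well, with differences of −0.74, −0.15 and −0.12. The other controls overlapped, and a second actin set lay the other way, by 0.60.

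**Figure D2:**
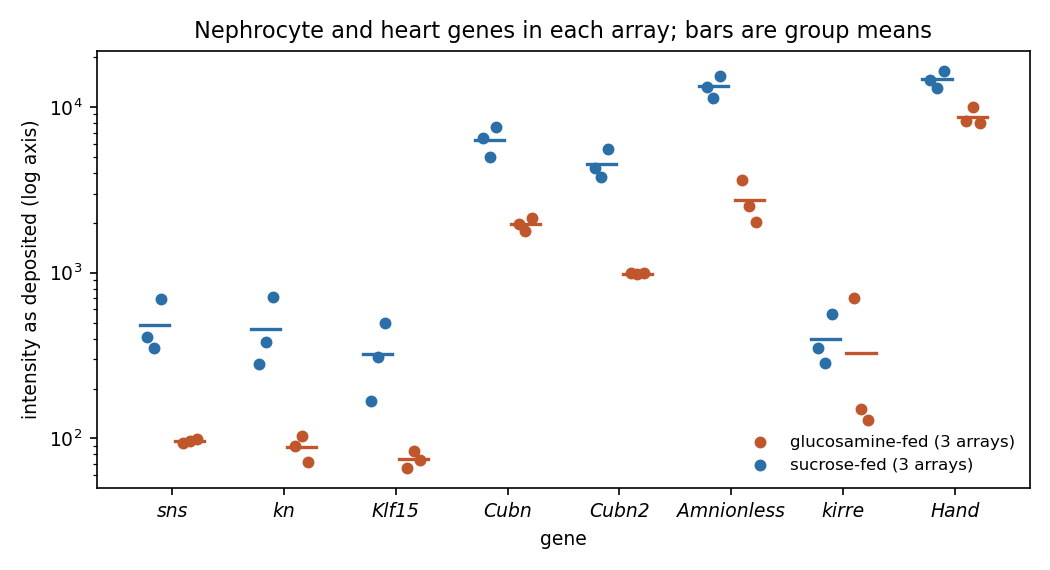
The vertical axis is intensity as deposited on a log axis, for 8 genes, with 1 point per array (3 glucosamine-fed, 3 sucrose-fed) and a bar at each group mean. For every gene shown except kirre the 3 glucosamine arrays lie below the 3 sucrose arrays, as for sns with means of 96.6 and 486.

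Among cardiac regulators and ion channels, 1 of 24 tested members rose, 2 fell and 21 did not pass, while adjusted over the list alone none rose and 2 fell. Hand, a transcription factor gene of heart and pericardial cells, fell from 14680 ± 1801 to 8729 ± 1061 (SD, n = 3 each; adjusted p = 0.0239). The potassium channel gene sei fell by 1.48 and Irk1 rose by 0.73 on the log2 scale, while Ork1 differed by −0.83 (adjusted p = 0.0528). Of 26 members of the sarcomere list, Mlc-c, a gene of a cytoplasmic myosin light chain, rose by 0.50 and none fell. Adjusted over the list alone none passed. TpnC73F (0.49), Zasp52 (0.33) and TpnC41C (−0.27) had overlapping groups. Camera adjusted p values were 0.591 for the cardiac list and 0.127 for the sarcomere list, and the sarcomere list had 0.00115 without glucosamine replicate 3 and 0.0307 without sucrose replicate 3. The sarcomere median was 0.25, and 0.03 without glucosamine replicate 2, and Mlc-c passed in none of the fits without 1 array. Without 1 array, 1 or 2 cardiac members fell, Irk1 passed only without glucosamine replicate 3, and Hand passed in 2 of the 6 fits and in 11 of 17 alternatives (adjusted p up to 0.144). Of 21 extracellular matrix genes, Loxl1, a lysyl oxidase gene, rose by 1.53, and the laminin gene wb and the integrin gene mew fell by 1.65 and 1.06. A second probe set of wb had −0.65 (adjusted p = 0.0839), while one of mew fell by 1.11, and mew passed in 2 of the 6 fits without 1 array. Adjusted over the list alone the same numbers passed, 1 up and 2 down, and Col4a1, a collagen gene, differed by 0.70 (adjusted p = 0.0722). The camera adjusted p of the matrix list was 0.114, and 0.00388 without glucosamine replicate 3, where 3 members rose and none fell. None fell without glucosamine replicate 1, and 1 fell without sucrose replicate 2 or 3.

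In the list of hexosamine synthesis and O-GlcNAc genes, 3 of 27 tested members rose and 6 fell, or 4 and 8 adjusted over the list alone. Gfat1, the rate-limiting enzyme gene of hexosamine synthesis, had an intensity of 640.4 ± 138 against 142 ± 51.0 (SD, n = 3 each; log2 difference 2.08 ± 0.27, SE; adjusted p = 0.00542). A second probe set of Gfat1 did not show this rise, with a log2 difference of −0.04 (adjusted p = 0.919). Nagk, which encodes a kinase of N-acetylglucosamine, rose by 1.25, while Idgf5, of the chitinase-like growth factors, fell by 1.76 and Mgat3, an N-acetylglucosaminyltransferase gene, by 1.11. Gfat2 (−0.52, adjusted p = 0.212), the O-GlcNAc transferase gene sxc (−0.14, adjusted p = 0.444) and Oga, the gene of the enzyme that removes O-GlcNAc (0.22, adjusted p = 0.566), did not pass. The camera adjusted p of the list was 0.414. The count of 6 falls was 3 without glucosamine replicate 1, glucosamine replicate 3, sucrose replicate 1 or sucrose replicate 3.

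4 lists of energy metabolism were called down by camera with a preset correlation, and none with an estimated correlation (adjusted p = 0.60 for each). In oxidative phosphorylation 19 of 32 members fell, or 27 adjusted over the list alone, and 31 had a negative difference, with a median of −0.68 (adjusted p = 3.1e-09). Examples were levy of complex IV (−1.04), RFeSP of complex III (−0.91), SdhC of complex II (−0.79) and ND-75 of complex I (−0.75), although a second probe set of RFeSP had −0.48 (adjusted p = 0.145). In the citrate cycle 3 of 12 fell, or 9 adjusted over the list alone, with a median of −0.50 (adjusted p = 0.00150); they were Idh3g (−0.90), ScsbetaG (−0.74) and Scsalpha1 (−0.67). In glycolysis 4 of 12 fell, or 6 adjusted over the list alone, with a median of −0.56 (adjusted p = 0.00981). These were Ald1 (−1.03), Pgk (−0.93), Tpi (−0.67) and Pgi (−0.63), and a second probe set of Ald1 differed by −0.09 (adjusted p = 0.715). In the pentose phosphate, gluconeogenesis and trehalose-glycogen list 1 of 27 rose and 6 fell, or 1 and 11 adjusted over the list alone (median −0.46, adjusted p = 0.00527). Rpi (−1.62), the sorbitol dehydrogenase gene Sodh1 (−1.61), the transketolase-like gene CG8036 (−0.97) and the glycogen synthase gene Glys (−0.94) fell. With an estimated correlation the unadjusted p was 0.0671 for oxidative phosphorylation and 0.0430 for the citrate cycle. The citrate cycle count of 3 was 1 in each fit without 1 array except that without glucosamine replicate 2, where it was 3. The glycolysis count of 4 was 1 without glucosamine replicate 1, glucosamine replicate 2 or sucrose replicate 2, 2 without sucrose replicate 1 or 3, and 3 without glucosamine replicate 3. The pentose phosphate count of 6 was 4 without glucosamine replicate 3 and 3 without any other single array. The count of 19 was 4 without glucosamine replicate 1, 9 without glucosamine replicate 3, 9 without sucrose replicate 1, 6 without sucrose replicate 2 and 10 without sucrose replicate 3, and 0 with glucosamine replicate 3 and sucrose replicate 1 both left out. The median of −0.68 was −0.65 with both left out and −0.71 to −0.59 without 1 array, so the calls were lost with fewer arrays while the median stayed near its value. The 5′ minus 3′ signals of the eIF-4a, GAPDH and 18S rRNA controls were also lower in the glucosamine arrays, with log2 differences of −0.74, −0.15 and −0.12. The other controls overlapped, and a second actin set lay the other way, by 0.60.

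**Figure D3:**
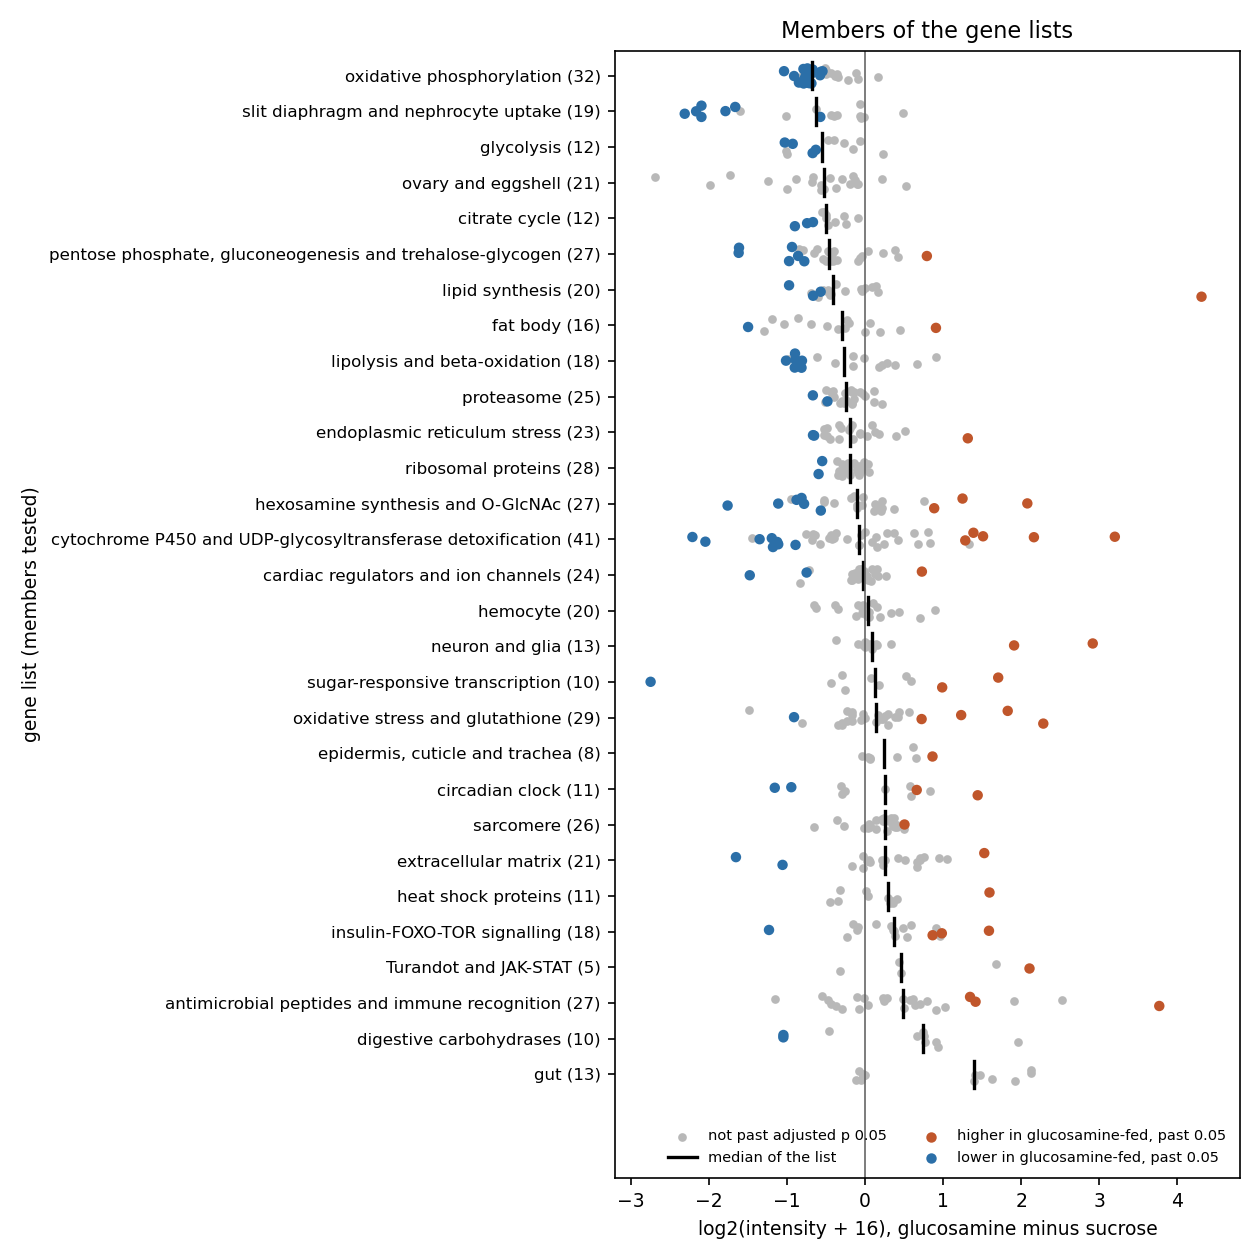
The horizontal axis is the difference of log2(intensity + 16) between glucosamine-fed and sucrose-fed flies, and each point is 1 tested member of the list named at the left, coloured where it passed an adjusted p of 0.05. Black marks are list medians, which run from −0.68 for oxidative phosphorylation to 1.40 for gut markers; the gut median was 0.02 without glucosamine replicate 3 and 2.21 without glucosamine replicate 1.

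In lipolysis and beta-oxidation 6 of 18 members fell and none rose, or 8 and 1 adjusted over the list alone, and the camera adjusted p of the list was 0.115. The count of 6 was 2 without glucosamine replicate 1 and 2 without sucrose replicate 2. The carnitine palmitoyltransferase gene whd (−1.01), Acox57D-d (−0.90), Acbp1 (−0.90) and Mtpbeta (−0.81) were among them, and a second probe set of whd had −0.59 (adjusted p = 0.0837). In lipid synthesis Dgat2 rose while 3 of 20 members fell, namely mdy (−0.97), which also encodes a diacylglycerol acyltransferase, ACC (−0.67) and ATPCL (−0.57). The count of 3 falls was 2 without glucosamine replicate 3 and 0 without any other single array, and ACC and ATPCL passed in none of these 6 fits. Adjusted over the list alone 1 rose and 7 fell. The median and mean differences were −0.41 and −0.10 (camera adjusted p = 0.0858, and 0.0461 without glucosamine replicate 3). Without sucrose replicate 2 the median was −0.25. Of insulin-FOXO-TOR genes, 3 of 18 rose and 1 fell, or 4 and 1 adjusted over the list alone. The insulin receptor gene InR rose by 1.59, REPTOR by 0.98 and the TOR inhibitor gene scyl by 0.87, and AkhR, the adipokinetic hormone receptor gene, fell by 1.23, with −0.37 (adjusted p = 0.161) in its second probe set. This was the one list called up (median 0.38, camera adjusted p = 0.0332, and adjusted p = 0.60 with an estimated correlation), and its adjusted p was 0.0529 without glucosamine replicate 1 and 0.0625 without sucrose replicate 1. Among sugar-responsive transcription genes, cbt (1.71) and Atf3 (0.99) rose and tobi fell, while Aldh-III differed by −0.43 (adjusted p = 0.0700). Atf3, AkhR and REPTOR each passed in 2 of the 6 fits without 1 array, and REPTOR in 11 of 17 alternatives (adjusted p up to 0.135). Of those 10 members, 2 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.662).

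The ribosomal protein and proteasome lists were called down by camera with a preset correlation but not with an estimated one (adjusted p = 0.776 for each), and 2 members of each list passed. Of 28 ribosomal protein genes RpLP0 and RpL34a fell, by 0.60 and 0.55, and the median was −0.19 (camera adjusted p = 0.0251). RpS7 (−0.36) and RpLP1 (−0.34) did not pass. Of 25 proteasome genes Rpn7 and Prosalpha7 fell, by 0.67 and 0.48, and the median was −0.24 (camera adjusted p = 0.0186), while Rpn12 (−0.50) and Prosalpha4 (−0.42) did not pass. In both lists none passed adjusted over the list alone, and in each fit without 1 array at most 1 member passed. Both calls ended under cyclic loess, with medians of −0.05 for ribosomal proteins (adjusted p = 0.585) and −0.14 for the proteasome (adjusted p = 0.168). The ribosomal call also ended without glucosamine replicate 2 (adjusted p = 0.110) or sucrose replicate 1 (adjusted p = 0.0892), and the proteasome call without glucosamine replicate 1 (adjusted p = 0.0529) or sucrose replicate 1 (adjusted p = 0.0858).

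Of 41 cytochrome P450 and UDP-glycosyltransferase genes 5 rose and 8 fell, or 9 and 9 adjusted over the list alone (camera adjusted p = 0.620). The count of 8 falls was 4 without glucosamine replicate 1 and 5 without sucrose replicate 2, and that of 5 rises was 3 without glucosamine replicate 1. Cyp6d2 rose by 3.20 ± 0.23 and Cyp4p1 by 2.16 ± 0.16, whereas Cyp6a2 fell by 2.21 ± 0.30 and Cyp6g1 by 2.05 ± 0.25 (SE). Of 29 oxidative stress and glutathione genes 4 rose and 1 fell, and the same numbers passed adjusted over the list alone (camera adjusted p = 0.414). GstD6 (2.28), GstD5 (1.83) and GstT1 (0.72) rose, and the mitochondrial superoxide dismutase gene Sod2 fell by 0.91 and passed in 3 of the 6 fits without 1 array. The count of 4 rises was 0 without glucosamine replicate 1, glucosamine replicate 3 or sucrose replicate 1, 1 without glucosamine replicate 2 and 2 without sucrose replicate 3. Of 11 members of the heat shock protein list, the co-chaperone gene stv rose by 1.59, also adjusted over the list alone (camera adjusted p = 0.319). Hsc70-4 (0.32), the transcription factor gene Hsf (0.30) and l(2)efl (0.36) did not pass. Of 23 endoplasmic reticulum stress genes the kinase gene PEK rose by 1.32 and Sec63 and P58IPK fell by 0.65 and 0.67, Der-1 differed by −0.48 (adjusted p = 0.0557), and none passed adjusted over the list alone (camera adjusted p = 0.235). PEK, Sec63 and P58IPK passed in 1, 1 and 0 of the 6 fits without 1 array, and stv in 2. Of 11 circadian clock genes vri (1.44) and dco (0.66) rose and Pdfr (−1.16) and cry (−0.94) fell, and the same numbers, 2 and 2, passed adjusted over the list alone (camera adjusted p = 0.620). Neither vri nor dco passed without glucosamine replicate 1, sucrose replicate 1 or sucrose replicate 2, and Pdfr passed in 1 of the 6 fits without 1 array and cry in all 6.

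Of 27 genes of antimicrobial peptides and immune recognition 3 rose and none fell, also adjusted over the list alone (camera adjusted p = 0.100). The list's adjusted p was 0.0181 without glucosamine replicate 1, 0.0191 without glucosamine replicate 3 and 0.0365 without sucrose replicate 1. Its median of 0.48 was −0.05 without glucosamine replicate 2, where 3 members rose and 2 fell. PGRP-SC2, which encodes an enzyme that cleaves bacterial peptidoglycan, had an intensity of 4764 ± 1747 against 373 ± 277 (SD, n = 3 each; log2 difference 3.77 ± 0.53, SE; adjusted p = 0.00671). The Toll ligand gene spz rose by 1.42 and the thioester protein gene Tep4 by 1.35, and dl differed by 0.71 (adjusted p = 0.105). In the Turandot and JAK-STAT list 1 of 5 members, vir-1, rose by 2.10, also adjusted over the list alone (camera adjusted p = 0.152). TotC differed by 1.68, dome by 0.47 and Stat92E by −0.32, and none of these passed.

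No list of markers of other cells that a dissection could carry passed the camera test with all 6 arrays, but single arrays stood apart. The mean log2 of gut markers was 4.89, 5.82 and 7.84 in the 3 glucosamine arrays and 5.01, 5.33 and 5.49 in the sucrose arrays, so glucosamine replicate 3 was far above the rest. None of 13 gut markers passed, over all genes or adjusted over the list alone (camera adjusted p = 0.414), and Jon65Aiii, yip7, betaTry and epsilonTry had log2 differences of 2.13, 2.13, 1.63 and 1.40. In the list of digestive carbohydrases Mal-A5 and Mal-B2 each fell by 1.05 among 10 members, also adjusted over the list alone, while Mal-A1 (1.96) and Mal-A3 (0.74) did not pass (camera adjusted p = 0.663). The mean log2 of ovary and eggshell markers was 7.05 in sucrose replicate 1 and 5.13 to 5.48 in the other 5 arrays. None of 21 ovary markers passed, over all genes or adjusted over the list alone (camera adjusted p = 0.141, with 0.0146 without sucrose replicate 2 and 0.0345 without sucrose replicate 3), and Cp19 (−2.69), otu (−0.89), Cp15 (−0.67) and bcd (0.52) had the smallest p. Of 16 fat body markers fit rose by 0.91 and NLaz fell by 1.50, and adjusted over the list alone none rose and 1 fell (camera adjusted p = 0.191). Mtp (−1.19) and Adgf-A (−0.86) did not pass, and fit passed in none of the 6 fits without 1 array. Mal-A5 and Mal-B2 passed in 3 and 2 of these fits. With glucosamine replicate 3 and sucrose replicate 1 both left out, 327 genes passed, 209 higher and 118 lower, and 316 of these were among the 1858. In that setting, fitted with the preset correlation only, 12 lists were called against 8. The lists called there but not with all 6 arrays were sarcomere (adjusted p = 0.00498), extracellular matrix (0.00498), antimicrobial peptides and immune recognition (0.00533) and lipid synthesis (0.0445).

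Of 13 neuron and glia markers futsch rose by 2.92 and cac by 1.91, also adjusted over the list alone (camera adjusted p = 0.235). Other probe sets of these genes did not pass, with 0.63 and −0.07 for futsch and 0.41 for cac, and Appl (0.33) and moody (−0.37) did not pass either. Of 8 markers of epidermis, cuticle and trachea serp rose by 0.85, also adjusted over the list alone (camera adjusted p = 0.141), while Gasp (0.65), obst-E (0.62) and Ddc (0.41) did not pass. None of 20 hemocyte markers passed, over all genes or adjusted over the list alone (camera adjusted p = 0.726), with 0.90 for NimC2, −0.65 for ush and −0.35 for Nplp2.

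Some control probe sets gave a sign of RNA or labelling quality that moved with the groups, while others overlapped. The log2 signal at the 5′ end minus that at the 3′ end of the eIF-4a control was −2.98 ± 0.33 in glucosamine-fed and −2.24 ± 0.12 in sucrose-fed flies (SD, n = 3 each), and the groups did not overlap. The GAPDH control was −1.50 ± 0.10 against −1.36 ± 0.02, also without overlap, and the 18S rRNA control was −0.76 ± 0.02 against −0.64 ± 0.07, again lower without overlap. The actin control overlapped, with −1.87 ± 0.28 against −1.60 ± 0.06. A second GAPDH set overlapped as well, with −2.97 ± 0.14 against −2.87 ± 0.14. A second actin set lay the other way, at −1.82 ± 0.17 against −2.42 ± 0.46, with overlap. The mean log2 of the hybridization spike controls was 12.90, 11.81 and 11.92 in glucosamine replicates 1, 2 and 3. It was 12.16, 12.20 and 12.37 in sucrose replicates 1, 2 and 3, so glucosamine replicate 1 was the highest. Whether this bears on the results was not tested.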

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

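The test in this part was not among the planned comparisons. Probe sets that the annotation assigns to several genes stayed outside the comparison, since no gene can be named from them. Tested in the same way, 61 of 295 such probe sets passed an adjusted p of 0.05, 32 higher and 29 lower in glucosamine-fed flies. Of all genes and unnamed probe sets tested, 18.5% passed. The report did not use these probe sets of several genes.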

How the results depend on the processing

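The setting that left out glucosamine replicate 3 and sucrose replicate 1 together was chosen after seeing the data; all other settings were planned. In the 17 settings that test 1 value per gene, the genes called here that were tested kept their sign, except 2 under the mean of a gene's probe sets. With all probe sets tested separately, 17 of 148 other probe sets of these genes had the opposite sign, 1 of them past the threshold. Over 142 named genes and 2399 values, 2044 kept their side of the threshold, 329 lost it, 26 gained it and 0 reversed; 35 of the 99 past the threshold stayed past it in every setting that gave a value. Counts under the 3 normalizations, no filter, the mean of probe sets, the variance trend, array weights, log2(intensity + 1) and separate probe sets ran from 1313 to 2012, against 1858. Without 1 array, as fewer arrays were fitted, the counts ran from 782 to 1465 in all, from 493 to 830 higher and from 289 to 635 lower, and from 6 to 12 lists. Without both arrays 327 genes passed, 209 higher and 118 lower, and 12 lists. At an unadjusted p under 0.05 there were 3300, 1665 higher and 1635 lower, where chance gives 501.1.

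Replicate numbers did not pair the arrays: same-numbered deviations correlated at 0.02, −0.12 and −0.05, and not every array correlated best with its own number (0.21 between glucosamine replicate 3 and sucrose replicate 2). The fit with the replicate block called 988 genes, 588 higher and 400 lower, and 7 lists, with the ribosomal protein list no longer called. A block also leaves less data to estimate the spread, so lost power cannot be told from an effect of pairing.

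For lists, leaving out the lowest 60% gave 5 calls in place of 8, and the cause was not tested. An estimated correlation, which was 0.252 for oxidative phosphorylation in place of 0.01, gave 0 calls. The 8 calls thus depend on the use of a preset correlation. A higher correlation was not the whole reason for their loss. The insulin-FOXO-TOR list had an estimated correlation of 0.00199, below the preset one. Its unadjusted camera p still went from 0.00915 with the preset to 0.0502 with the estimate. Fry gave 9. Of 547 list values 505 kept their side, 24 lost it, 18 gained it and 0 reversed. A value past the threshold in neither setting counts as kept even where its sign differed, as for 16 list values and 3 values of named genes. The 60% filter left 15 named genes without a value. Signal over background limits genes of low intensity.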

Other observations

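The tests of the sarcomere, nephrocyte, fat body and level-matched lists, and the lists of the ecdysteroid kinase-like family and of ribosome biogenesis, were chosen only after the results that prompted them were seen; the members counted for those 2 families leave out those already seen. The bound used for the chromosome region was made stricter after its first value was seen.

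Some factors of ribosome assembly were higher in glucosamine-fed flies. Whether the 5′ to 3′ differences of the controls, some of which moved with the groups, bear on this was not tested. Among 44 ribosome biogenesis genes not seen before the test, 12 rose, 1 fell and the rest did not pass, which is 27.3% higher against 9.93% of all tested genes (Fisher's exact test, p = 8.96e-04, which treats genes as independent). eIF6 rose by 2.14, Nop56 by 1.77, Nop60B by 1.72 and RIOK2 by 0.95, and Non1 fell by 0.75 on the log2 scale. The median difference was 0.59, and 0.54 to 0.60 with 11 to 13 genes higher under the other scalings, and camera gave a p of 3.3e-07 with a preset correlation and a p of 0.324 with an estimated correlation. The count goes with the hypothesis that ribosome biogenesis genes are higher as a group, but the test with an estimated correlation does not set the list apart from other genes, while the ribosomal proteins themselves had a median of −0.19.

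A second hypothesis was that the ecdysteroid kinase-like family, which holds 4 of the 12 largest rises, is higher as a whole. Among 35 members not seen before, 7 rose and 1 fell, which is 20% against 9.93% (Fisher's exact test, p = 0.0787). The median difference was 0.33, and camera gave a p of 0.0205 with a preset correlation and a p of 0.289 with an estimated correlation, so the tests did not decide it. CG31436 rose by 1.43, CG31097 by 1.84 and CG31380 by 1.70, and CG5126 fell by 1.36 on the log2 scale.

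The rises of over 8-fold numbered 35 against 2 falls of that size, and 26 of the 35 have a symbol. Gut RNA in the glucosamine arrays is argued against as the whole cause. The gut marker mean of glucosamine replicate 1, 4.89, was not above the sucrose arrays. These genes had a median there of 4.13 above the sucrose mean. They were chosen as higher in these same arrays, which made a high median in that array likely. A part played by gut RNA, as in single genes or in glucosamine replicate 3, stays open. A different genetic background confined to 500 neighbouring genes is argued against as the whole cause too. The densest window of that size held 7 of 26, or 26.9%, where over 50% was required. The 95% Wilson interval of 13.7% to 46.1% treats genes as independent and ignores that the densest window was picked. A wider region was not tested and stays open. Random genes gave a median of 19.2% with a permutation p of 0.0351, so a linked difference in part of these genes stays open, as does a background that differs genome-wide. The diet as a biological cause is a hypothesis that remains open beside them. The 5′ to 3′ differences of the controls were not tested as a cause of these rises.

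The fall of nephrocyte genes was weighed against dissection. Dilution by RNA of non-muscle tissue is argued against as the whole cause. The sarcomere list's mean difference exceeded that of the nephrocyte list by 1.15 ± 0.19 (SE), without overlap of the arrays. The sarcomere means of glucosamine replicates 1 and 2, 10.15 and 10.36, lay above every sucrose array (9.74 to 10.08). In glucosamine replicate 3, with the high gut markers, the sarcomere mean was 9.64, below them. Its nephrocyte mean of 8.16 was the lowest of all arrays, so some dilution in that array stays open. A smaller share of nephrocytes in the glucosamine complexes cannot be told apart from lower expression per cell, because all 7 nephrocyte-restricted members had negative differences, from −2.31 to −1.01; 6 of them passed the threshold, and Mec2 did not (−1.01, adjusted p = 0.0583). The 5′ to 3′ difference of the eIF-4a control was not tested as a cause. An effect of the diet on nephrocytes stays an open hypothesis.

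The fall of oxidative phosphorylation genes was weighed against normalization and tissue. A level-dependent shift is argued against, since 0% of 10000 random lists of like mean level had a median as low as −0.68, the lowest being −0.52, and the median under cyclic loess was −0.56. A smaller share of fat body cannot be told apart, since the fat body median of −0.30 lay above that of the list by 0.38 with a bootstrap SE of 0.22. That SE comes from resampling genes, which it treats as independent, and does not measure the spread between arrays. The gap between the 2 medians moved with single arrays. The fat body median was −0.18 without sucrose replicate 2 and −0.43 without sucrose replicate 1, where the list had −0.62 and −0.63. The 5′ to 3′ difference of the eIF-4a control, which also moved with the groups, was not tested as a cause. A difference in metabolism between the diets is a hypothesis that stays open.

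The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 1858 genes and the highest other split 0, so 1 of 10 splits gave as many. For gene lists the real split called 8 and the highest other 16, and 5 of the 10 splits gave as many. List calls in as large a number thus also came from groupings that mix the diets. Every split but the real one has both diets on each side. The diet difference then widens the spread within a side, which works against gene calls. Part of it, and single arrays that stand apart, can also remain between the sides. These splits therefore do not show what chance alone gives, for genes or for lists.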
